A study of Mus musculus with 12 samples.

How the data were processed

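The series holds 8 RNA-seq libraries, 2 for each combination of stage (pre-pro-B, small pre-B) and genotype (WT, KO), and 4 Hi-C samples. Cells were sorted from mouse bone marrow, the gates are not given in the labels, and poly(A) RNA was made into libraries that do not keep the strand. No processed Hi-C files were among the files used here, so these samples were left out. Per the labels, the tools used by the authors were Trimmomatic, HISAT2 2.1.0, featureCounts 1.6.1 and DESeq2 for RNA-seq, with Bowtie2, SAMtools 1.9 and Juicer 1.22.01 named besides, on the GRCm38 build. The deposited values are raw counts per Ensembl gene, whole numbers summed over the exons of each gene, in a file per library. The strand setting, the handling of reads that map to several places and the annotation release are not stated in the sources used here. Reads shared between near-identical immunoglobulin segments are therefore counted in an unknown way, and sums over segment families were tested beside single segments. A total of 86 genes on unplaced scaffolds hold counts in the pre-pro-B libraries and 0 in all small pre-B libraries. This argues against equal handling of reads on these scaffolds at both stages, which the sources used here do not describe.

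The 8 files were joined on the gene identifier (54532 genes), and 54409 identifiers were matched to gene symbols. Totals ranged from 18228012 to 23748426 counts per library. Intervals on counts are 95% exact Clopper-Pearson intervals, and a count of 0 was read as an upper limit of 3 counts over the group. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No pair of libraries was a duplicate.

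Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr (minimum count 10), which left 17580, and scaled with TMM. All 8 libraries entered a quasi-likelihood fit with a mean per group and 4 residual degrees of freedom. The contrasts were KO against WT at each stage, the difference of these effects (small pre-B minus pre-pro-B) and small pre-B against pre-pro-B in WT. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM use TMM-scaled library sizes. With 2 libraries per group an exact permutation test cannot pass the threshold, so none is given for single values.

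Before the data were examined, 34 gene lists were fixed: markers of other marrow cells (plasmacytoid dendritic, T and NK, neutrophil and monocyte, erythroid, mast cell, basophil and eosinophil, plasma cell, stromal and endothelial), B lineage stages and transcription factors, splicing complexes, recombination and chromatin loop factors, cell cycle, histones, p53 targets, the BCL2 family, MYC, interferon, integrated stress and unfolded protein response (called the stress response list), immediate early genes, multipotent progenitors, mitochondrial mRNAs, immunoglobulin segments and constant genes, and the 2 Cre host genes. Lists of at least 5 tested members (33) were tested with camera at a preset correlation of 0.01, adjusted over lists. Of the lists called, 5 of 22 for pre-pro-B KO, 0 of 19 for small pre-B KO, 3 of 18 for the difference and 0 of 17 for the WT stages held with an estimated correlation. Fry, which asks if the genes of a list move on balance in 1 direction and does not compare them with other genes, called 5, 1, 3 and 19. Sums over immunoglobulin segment families entered a separate fit in place of their members, with the library sizes kept. For lists with members at 0 counts in a group, medians are given with these members at the bound set by 3 counts, and members at or under 3 counts in both groups left out.

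The rule for named genes was also fixed before the data were examined. It takes Usp39, the 8 genes of largest rise and the 8 of largest fall among those called with a mean of at least 5 CPM in the higher group and no overlap of libraries, without immunoglobulin segments, histones and predicted genes, and up to 4 called members per list (2 of smallest p where none was called). For the difference between stages and the WT stages it takes the 5 largest in each direction. Because the 8-library fit called no gene for small pre-B KO, the rule was applied there to the fit of the 4 libraries of the stage. Igha, Ighm, Ighd, Rpl36a-ps3, Gm8225, Gm2606, Gm12070 and the genes shared by both fits were named after their values were seen.

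Each fit was tested on simulated data with 100 genes changed 2-fold and about as many changed 4-fold. The 8-library fit recovered 38% of 2-fold and 86% of 4-fold changes for pre-pro-B KO, with 10 of 134 calls at unchanged genes, and 32% and 84% for small pre-B KO, with 19 of 135 calls at unchanged genes. The 4-library fit recovered 32% and 77.8% for pre-pro-B KO (7 of 116 calls at unchanged genes) and 73.7% and 97% for small pre-B KO (31 of 200). With no change simulated, the 8-library fits called 0 genes and the 4-library fits 4 and 10. The simulated genes were independent, and each gene had the same spread in all libraries of a fit. In the real data the biological coefficient of variation was 23.1% at the pre-pro-B and 13.5% at the small pre-B stage. The simulated rates of false calls therefore need not hold for the real libraries.

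Alternatives were DESeq2 size factors, no filter on low counts, a stricter filter (a mean of at least 1 CPM), DESeq2, limma-voom, the 4 libraries of a stage alone, the replicate number as a block, immunoglobulin genes left out, a fold threshold and leaving out each library. Leaving out each library from the 4-library fits, and DESeq2 and limma-voom on 4 libraries, were added after the data had been seen. Where a library was left out, the lone library of its group was assumed to vary like the other groups. The labels do not pair the libraries, and the values did not show that replicate numbers pair them. Bootstrap intervals use 10000 resamples of list members, or 1000 resamples of all genes. Figures were drawn with Python and matplotlib.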

Results

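RNA was sequenced from B lineage precursors sorted from the bone marrow of C57BL/6 mice at the pre-pro-B and the small pre-B stage. Mice with floxed Usp39 alleles and no Cre (WT) were compared with floxed mice carrying a Cre recombinase (KO), which was mb1-cre at the pre-pro-B stage and cd19-cre at the small pre-B stage. Usp39 is a component of the spliceosome, and the title of the series ties it to rearrangement of the immunoglobulin genes in B cell development. The 8 libraries formed 4 groups of 2. The totals ranged from 18228012 to 23748426 counts per library over 54532 genes. In this order, the pre-pro-B WT libraries held 21712325 and 22463875 counts and the pre-pro-B KO libraries 23748426 and 19220152. The small pre-B WT libraries held 18228012 and 21261984 counts and the small pre-B KO libraries 20147094 and 22255835. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. No group carried Cre without floxed Usp39, so every KO comparison also compares presence with absence of Cre, and the 2 Cre lines differ between the stages. Hi-C samples of pre-pro-B cells are listed in the series, but no processed Hi-C files were among the files used here, so they were not analysed.

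The targeted gene was not detectably lower in the libraries labelled KO. Usp39 (ENSMUSG00000056305, GRCm38 chromosome 6, 72318678 to 72345184) had 47.6 ± 8.3 counts per 1000000 (CPM) in pre-pro-B WT and 42.3 ± 0.9 CPM in pre-pro-B KO (mean ± SD, n = 2 per group). The log2 fold change was -0.17 (SE 0.14, adjusted p = 0.968), and it ranged from -0.34 to 0.02 when single libraries were left out. At the small pre-B stage Usp39 had 71.8 ± 3.4 CPM in WT and 72.0 ± 2.2 CPM in KO, with a log2 fold change of 0.00 (SE 0.14, adjusted p = 1). A count per gene covers all 13 exon blocks and also counts exons outside a deleted part. The host genes of the Cre alleles were measured as well. Cd79a, which hosts mb1-cre, had log2 fold changes of -0.57 (SE 0.31) at the pre-pro-B and -0.78 (SE 0.30) at the small pre-B stage, and Cd19, which hosts cd19-cre, had 0.36 (SE 0.83) and -0.52 (SE 0.78), none past the threshold. At the pre-pro-B stage Cd79a had 32.2 and 48.5 CPM in WT and 18.8 and 35.8 CPM in KO, so the libraries overlapped. A single library set the direction of Cd19 at that stage, where the KO libraries had 2.7 and 34.9 CPM. The log2 fold change of Cd19 was -2.44 without KO replicate 2 and 1.26 without KO replicate 1. In the fit of the 4 small pre-B libraries alone, described below, Cd19 was called lower (-0.57, SE 0.10, adjusted p = 0.0499) and Cd79a was not (-0.83, SE 0.16, adjusted p = 0.0547).

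Marker genes showed which cells the libraries drew on. The pre-pro-B libraries held 2547 to 3106 CPM of Siglech, a surface receptor of plasmacytoid dendritic cells, against 93.7 to 104.9 CPM in the small pre-B libraries. Markers of plasmacytoid dendritic cells made up 1.77 to 2.05% of counts in the 4 pre-pro-B libraries. The small pre-B libraries held 14430 to 22700 CPM of S100a9, an abundant granule protein of neutrophils, and neutrophil and monocyte markers made up 6.71 and 5.83% of counts in WT and 8.73 and 8.49% in KO. In the pre-pro-B libraries the same markers made up 0.764 and 0.886% in WT and 0.426 and 0.149% in KO.

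**Figure D1:**
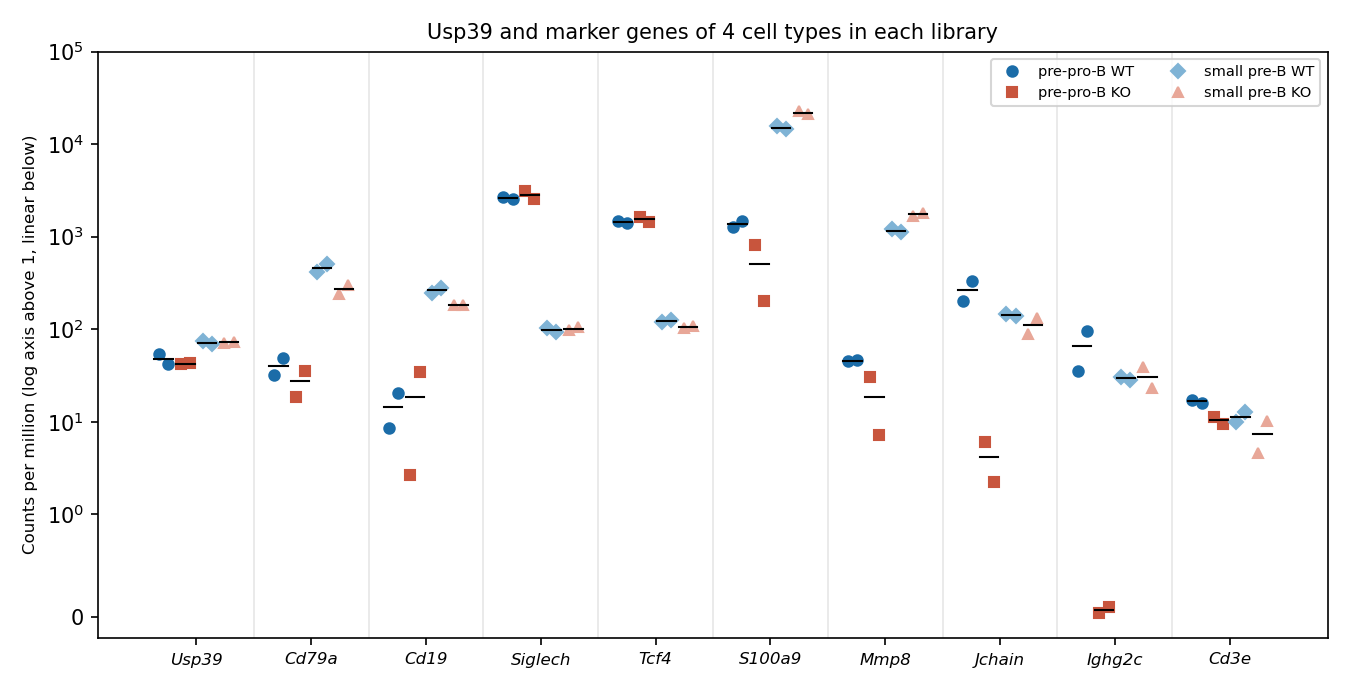
CPM of Usp39 and of marker genes in each library, on an axis that is logarithmic above 1 and linear below. Each point is a library, and black lines are means of the 2 libraries of a group. Usp39 lies between 41.7 and 74.2 CPM in all 8 libraries, while Jchain and Ighg2c lie lowest in the pre-pro-B KO libraries.

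At the pre-pro-B stage the question was which transcripts changed with the mb1-cre KO. The largest differences were in transcripts of immunoglobulin variable segments and of several constant genes, which were lower in the KO libraries. Counts per gene do not tell rearranged from unrearranged segments. Variable segments of the heavy chain locus were counted by family. The distal families (Ighv1 and Ighv8) had 14344 counts over both WT libraries and 369 over both KO libraries, a log2 fold change of -5.27 (SE 0.52, adjusted p = 0.00564). The proximal families (Ighv2 and Ighv5) had 1912 WT counts and 3 KO counts, a ratio of 620 with a 95% counting interval of 212 to 3010 (adjusted p = 0.00013). The other Ighv families fell by 5.88 on the log2 scale (SE 0.43, adjusted p = 0.00147), and the kappa variable segments (Igkv) fell by 5.21 (SE 0.48, adjusted p = 0.00461). By contrast, the summed D and J segments of the heavy chain locus had 152.7 ± 28.3 CPM in WT and 193.2 ± 101.3 CPM in KO (log2 fold change 0.34, SE 0.31, adjusted p = 0.996), and the kappa J segments had a log2 fold change of 0.56 (SE 0.21, adjusted p = 0.575). The lambda V and J segments had -0.73 (SE 0.32, adjusted p = 0.717). Within that sum Iglv1 had 1751 WT counts and 16 KO counts, while 3 of the 6 members tested were higher in KO. The lambda constant gene Iglc1 had 1735 WT counts and 104 KO counts (log2 fold change -4.04, adjusted p = 0.00659).

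**Figure D2:**
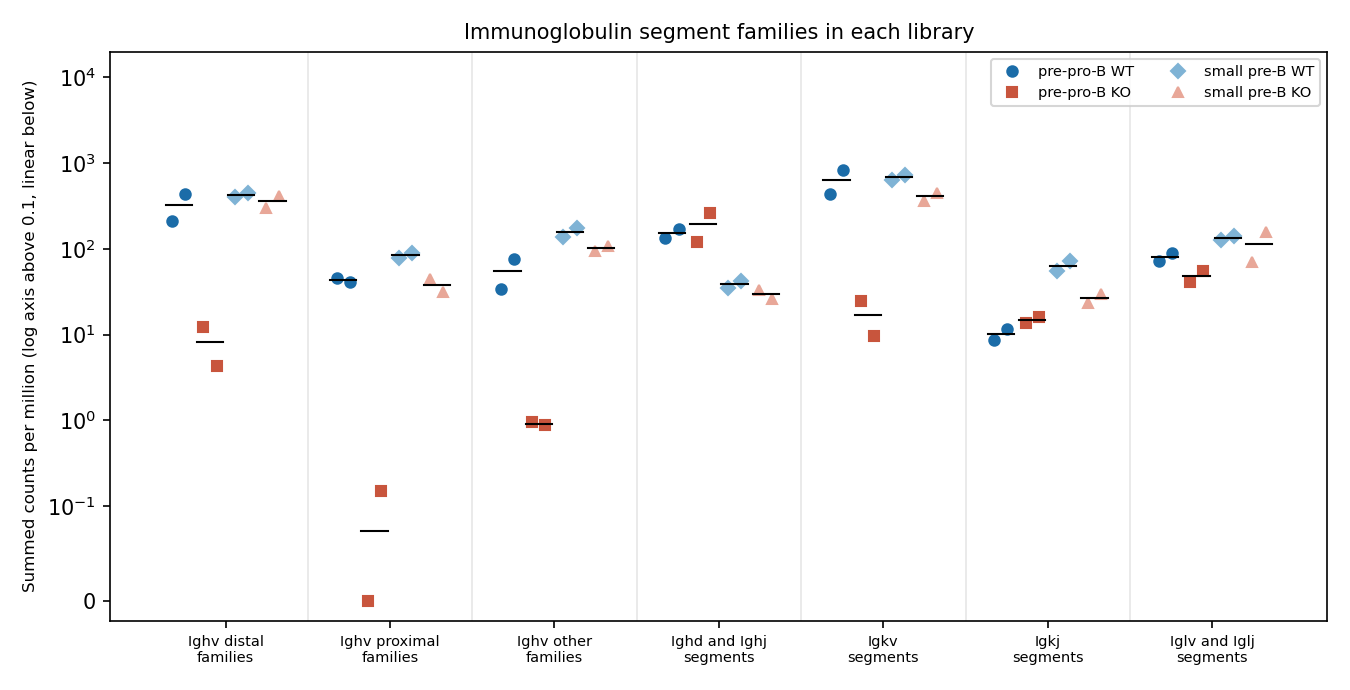
Summed CPM of immunoglobulin segment families in each library, on an axis that is logarithmic above 0.1 and linear below. Each point is a library, and black lines are means of the 2 libraries of a group. The pre-pro-B KO libraries lie below all other libraries for the Ighv and Igkv families, with 0 and 3 counts for the proximal Ighv families. They also lie below all others, by a smaller margin, for the lambda segments, but not for the heavy chain D and J or the kappa J segments.

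Single segments and constant genes showed the same picture. Of the 55 genes called at this stage, 29 were immunoglobulin genes, all lower in KO, and 13 of these had 0 counts in both KO libraries. Against a floor of 3 counts over the group, Ighv5-6 was at least 305-fold lower in KO, Ighv1-55 at least 214-fold, Ighv3-6 at least 188-fold and Igkv12-46 at least 181-fold. Of the class-switched constant genes, 3 fell as well, with 2931 WT counts against 3 KO counts for Ighg2c (ratio 950, 95% counting interval 325 to 4610) and 1507 against 2 for Ighg1 (ratio 733, 203 to 6060). Ighg2b fell less and kept 629 KO counts against 5048 in WT (log2 fold change -2.94, adjusted p = 0.0305). Igkc, the kappa constant gene, fell from 904 ± 382 to 85.9 ± 45.5 CPM, a log2 fold change of -3.39 (SE 0.42, adjusted p = 0.0146). Igha had 1365 and 2797 CPM in WT and 42.2 and 0 CPM in KO without passing the threshold (adjusted p = 0.192). Ighm (log2 fold change 0.06, SE 0.21) and Ighd (-0.15, SE 0.22), the constant genes used before class switching, did not pass it either.

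As lists, 9 of 58 distal Ighv segments, 1 of 15 proximal, 1 of 24 other Ighv and 12 of 84 Igkv segments were called lower, and 40, 11, 13 and 49 when adjusted over the list alone. With genes at 0 counts set to their bound, the list medians were -4.42, -3.83, -3.83 and -5.04 on the log2 scale. All 4 lists passed camera, and passed it with an estimated correlation as well (adjusted p = 0.00254, 0.00889, 0.0328 and 0.00254), and kept their calls without any single library. Medians of fitted values, in which members at 0 counts are not set to a bound, moved from -4.93 to -3.12 (distal) and from -5.66 to -3.12 (Igkv) without pre-pro-B WT replicate 2. The proximal one moved from -7.24 to -4.48 without WT replicate 1 and to -4.79 without WT replicate 2. The immunoglobulin constant genes, with 5 of 11 called lower and 7 over the list alone, had a median of -3.39 (adjusted p = 0.0195 with an estimated correlation). Of the lambda V and J list only Iglv1 was called (log2 fold change -6.72, SE 0.51), and its 6 members had a median of 0.00 and a mean of -0.94, tested as lower (camera adjusted p = 0.00802, adjusted p = 0.443 with an estimated correlation). The heavy chain D and J list did not pass (median 0.35, adjusted p = 0.19). The 5 kappa J segments were higher as a list, with a median of 0.56 (adjusted p = 0.00968, and adjusted p = 0.387 with an estimated correlation). The kappa J list lost its call without pre-pro-B WT replicate 1 (0.24) or KO replicate 2 (0.32), and the lambda list without WT replicate 2 (0.15) or KO replicate 1 (0.02).

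Outside the immunoglobulin genes, 26 genes were called in pre-pro-B cells. Jchain, the chain that joins polymeric antibodies and is made by antibody-secreting cells, fell from 266.4 ± 91.6 to 4.2 ± 2.7 CPM (log2 fold change -5.98, SE 0.47, adjusted p = 0.00134). Thbs1, a secreted matrix glycoprotein, fell by 2.54 (SE 0.40), Rhou, a small GTPase, by 1.95 (SE 0.25), and Tent5c, a poly(A) polymerase of antibody-secreting cells, by 1.70 (SE 0.23). Dach1, Slco4c1, St3gal5 and Lrrk2 fell by 1.47 to 1.68, and the lowest of their levels in WT was 5.4 CPM. The 5 genes called higher were Iigp1, an interferon-inducible GTPase, which rose from 16.97 ± 3.28 to 44.5 ± 8.7 CPM (log2 fold change 1.39, SE 0.21, adjusted p = 0.0382), and 4 pseudogenes or predicted genes. These were Gm8225 (log2 fold change 6.54, 6 WT counts against 565 KO counts), Rpl36a-ps3 (3.05), Gm2606 (1.27) and Gm12070 (1.22), named after their values were seen.

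Markers of other marrow cells also moved. All 24 neutrophil and monocyte markers were lower in KO, none called over all genes and 16 when adjusted over the list alone, with a median of -1.31 (adjusted p = 6.19e-30, and adjusted p = 0.186 with an estimated correlation). Ltf went from 1168 ± 227 to 301.4 ± 184.2 CPM and Ngp from 1457 ± 160 to 434.8 ± 236.9 CPM, both granule proteins. Among plasma cell markers, 9 of 10 were lower, with a median of -0.69 (adjusted p = 7.95e-10, and adjusted p = 0.132 with an estimated correlation). All 15 erythroid markers were lower, with a median of -1.54 (adjusted p = 6.66e-12, and adjusted p = 0.383 with an estimated correlation). T and NK cell markers had a median of -0.40 (adjusted p = 1.44e-04, and adjusted p = 0.519 with an estimated correlation). Mast cell, basophil and eosinophil markers had a median of -0.19 (adjusted p = 0.00883, and adjusted p = 0.501 with an estimated correlation). Single libraries moved these medians. Without pre-pro-B KO replicate 1 they were -2.24 for neutrophils and monocytes, -1.11 for plasma cells, -2.34 for erythroid cells, -0.71 for T and NK cells and -2.92 for the mast cell list. Without KO replicate 2 they were -0.73 for neutrophils and monocytes and -0.83 for erythroid cells, while T and NK cells (-0.12) and the mast cell list (0.70) lost their calls. Without WT replicate 1 erythroid cells were at -0.57, while T and NK cells (-0.18) and the mast cell list (-0.15) lost their calls. Plasmacytoid dendritic cell markers (median 0.13, adjusted p = 0.0617) and stromal and endothelial markers (0.41, adjusted p = 0.162) did not pass.

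Interferon-stimulated genes were higher in pre-pro-B KO in 27 of 29 members, none called over all genes and 15 when adjusted over the list alone, with a median of 0.63 (adjusted p = 6.83e-19, and adjusted p = 0.157 with an estimated correlation). Mx1 had 65.4 ± 3.6 CPM in WT and 106.5 ± 15.6 CPM in KO. The Pro-B and pre-BCR genes had a median of 0.20 (adjusted p = 0.00567, and adjusted p = 0.491 with an estimated correlation). Immediate early and heat shock genes had a median of -0.29 (adjusted p = 1.52e-06, and adjusted p = 0.132 with an estimated correlation). S phase genes were at 0.28 (adjusted p = 9.7e-06, 0.473 with an estimated correlation), G2 and mitosis genes at -0.20 (0.00122, and 0.578 with an estimated correlation) and replication-dependent histones at -0.48 (4.03e-05, and 0.47 with an estimated correlation). MYC and ribosome biogenesis genes were at 0.16 (0.00192, and 0.473 with an estimated correlation), U1 and U2 snRNP and SR proteins at 0.14 (0.00122, and 0.387 with an estimated correlation), and mitochondrially encoded mRNAs at -0.29 (0.0377, and 0.619 with an estimated correlation). The late pre-B and immature B genes had a median of 0.03 and a mean of -0.59, tested as lower (adjusted p = 0.0182, and adjusted p = 0.578 with an estimated correlation).

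Of these lists, only the interferon-stimulated and the immediate early and heat shock genes kept their calls without any single pre-pro-B library. Their medians were 0.39 for interferon without KO replicate 1, and -0.55, -0.45 and -0.54 for immediate early genes without WT replicate 1, KO replicate 1 and KO replicate 2. Without WT replicate 1 the Pro-B and pre-BCR (0.24), G2 and mitosis (0.05) and mitochondrial (0.11) lists lost their calls, and the late pre-B median was -0.05. Without WT replicate 2 the S phase (0.06), MYC (0.10), U1 and U2 (0.06) and late pre-B (0.11) lists lost theirs, while Pro-B genes were at 0.44, G2 and mitosis at -0.45 and mitochondrial mRNAs at -0.60. Without KO replicate 1 the G2 and mitosis (-0.07) and U1 and U2 (0.13) lists lost theirs, while Pro-B genes were at 0.52, late pre-B genes at -0.14, histones at -0.80 and mitochondrial mRNAs at -0.82. Without KO replicate 2 the Pro-B and pre-BCR (-0.19), late pre-B (0.02), S phase (0.09), histone (-0.28), MYC (0.08) and mitochondrial (0.10) lists lost theirs, and G2 and mitosis genes were at -0.33. Lists that did not pass in the main fit included the U4/U6.U5 tri-snRNP, the complex Usp39 belongs to (median 0.15, adjusted p = 0.0564), V(D)J recombination and end joining (0.00, 0.716), chromatin loop and locus contraction factors (0.03, 0.533) and B lineage transcription factors (-0.05, 0.161). Multipotent progenitor genes (0.08, 0.139), p53 target genes (0.01, 0.312), the BCL2 family (-0.09, 0.687) and the stress response list (0.08, 0.421) did not pass either.

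In all, 55 of 17580 genes were called in pre-pro-B cells by edgeR, 5 higher and 50 lower, and 54 of them changed at least 2-fold. The count depended on the method and on single libraries: it was 338 by DESeq2, 12 by limma-voom, 9 with immunoglobulin genes left out, 111 without pre-pro-B WT replicate 1 and 557 without pre-pro-B KO replicate 1. The 8-library fit had 1280 genes at an unadjusted p below 0.05 against 879 expected. A fit of the 4 pre-pro-B libraries alone had 664 such genes against 810 expected, so no excess. It called 37 genes, 28 of them shared, which kept Jchain, Reln, Gm8225 and Rpl36a-ps3. It did not keep Thbs1, Rhou, Tent5c, Dach1, Slco4c1, St3gal5, Lrrk2 or Iigp1. Over 16 alternative settings Jchain was called in all, Rhou in 13, St3gal5 in 10, Tent5c and Dach1 in 8, Iigp1, Thbs1 and Slco4c1 in 6 and Lrrk2 in 5, and none of these 9 genes changed sign.

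At the small pre-B stage the question was which transcripts changed with the cd19-cre KO. The fit of all 8 libraries by edgeR called 0 genes, with 1804 genes at an unadjusted p below 0.05 against 879 expected. DESeq2 called 160 genes and limma-voom 0. The spread was larger at the pre-pro-B stage, with a biological coefficient of variation of 23.1% against 13.5%, and a fit of the 4 small pre-B libraries alone called 239 genes, 93 higher and 146 lower in KO. That count was 5 without small pre-B WT replicate 2, 37 without WT replicate 1 and 1569 without KO replicate 2, and on simulated data the 4-library fit gave 31 false calls among 200. The genes in the next paragraph are those of the 4-library fit.

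Among the genes the rule named in small pre-B KO, Fosb, an immediate early transcription factor, fell from 145.9 ± 24.7 to 17.6 ± 2.2 CPM (log2 fold change -3.10, SE 0.15, adjusted p = 0.0026), and Cd69, an early activation antigen, from 93.2 ± 15.9 to 17.9 ± 2.7 CPM (log2 fold change -2.43, SE 0.16, adjusted p = 0.00867). Fcer2a, the low-affinity IgE receptor of mature B cells, fell by 1.92 (SE 0.24, adjusted p = 0.0378) and Cr2, a complement receptor of mature B cells, by 1.96 (SE 0.34, adjusted p = 0.0499). Rgs1, Ptgs2, Cacna1i and Plk2 fell by 1.71 to 2.14. Mid1, a ubiquitin ligase, rose from 18.4 ± 1.9 to 112 ± 47.3 CPM (log2 fold change 2.54, SE 0.27, adjusted p = 0.0287). The other named genes that rose were the cystatins Stfa1 (1.23) and Stfa2l1 (0.94), Asprv1 (1.01), S100a6 (0.91), the chemoattractant receptor Fpr1 (0.83), Cd101 (0.82) and Acvrl1, a receptor of the TGF-beta family (1.11).

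Lists were tested in the fit of all 8 libraries, where no member was called over all genes. Late pre-B and immature B genes were lower as a list, in 20 of 22 members and in 16 adjusted over the list alone, with a median of -0.96 (adjusted p = 1.4e-27, and adjusted p = 0.145 with an estimated correlation). Fcer2a had a log2 fold change of -1.87 (SE 0.25), and Ciita, the activator of MHC class II genes, -1.37 (SE 0.19). B lineage transcription factors were lower too, with a median of -0.50 (adjusted p = 2.1e-07, and adjusted p = 0.294 with an estimated correlation), and Zfp318 had -1.34 (SE 0.21) and Ikzf3 -0.85 (SE 0.17). The Pro-B and pre-BCR list did not pass (median 0.00, adjusted p = 0.326), with 11 members higher and 10 lower. Immediate early and heat shock genes had a median of -0.93 (adjusted p = 2.04e-12, and adjusted p = 0.0845 with an estimated correlation). Neutrophil and monocyte markers were higher in 23 of 24 members, with a median of 0.57 (adjusted p = 9.69e-04, and adjusted p = 0.741 with an estimated correlation). Markers of other cells were lower or did not pass: erythroid (-0.34, adjusted p = 0.0404, 0.799 with an estimated correlation), T and NK cells (-0.18, adjusted p = 0.00974, 0.782 with an estimated correlation), plasma cells (-0.47, adjusted p = 4.13e-05, 0.289 with an estimated correlation), mast cells, basophils and eosinophils (0.25, adjusted p = 0.875), plasmacytoid dendritic cells (0.11, adjusted p = 0.253) and stroma and endothelium (-0.43, adjusted p = 0.0978). The erythroid list lost its call without small pre-B WT replicate 1 (-0.23), WT replicate 2 (-0.30) or KO replicate 2 (-0.24), and T and NK cells without WT replicate 2 (-0.13) or KO replicate 1 (-0.01), with -0.27 without WT replicate 1 and -0.31 without KO replicate 2. B lineage transcription factors were at -0.33 without WT replicate 2 and plasma cell markers at -0.72 without KO replicate 2, both still called.

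Log2 fold changes of the summed Ighv and Igkv families were nearer to 0 here than in pre-pro-B KO. The proximal Ighv families had 83.9 ± 7.4 CPM in WT and 37.7 ± 9.2 CPM in KO, a log2 fold change of -1.16 (SE 0.23, adjusted p = 0.251) that passed in the 4-library fit at -1.21 (adjusted p = 0.0329). The distal families had 427.3 ± 28.9 and 358.7 ± 84.7 CPM (log2 fold change -0.25, SE 0.43, adjusted p = 0.891). Kappa J segments went from 63.5 ± 11.7 to 26.7 ± 4.7 CPM (-1.25, SE 0.20, adjusted p = 0.183, and -1.30 with adjusted p = 0.0329 in the 4-library fit). Igkv segments had -0.74 (SE 0.40, adjusted p = 0.568, and -0.80 with adjusted p = 0.0443 in the 4-library fit). The other Ighv families had -0.64, the heavy chain D and J segments -0.41 and the lambda segments -0.26, none past the threshold. As lists, the distal Ighv (median -0.28), proximal Ighv (-1.16), other Ighv (-1.14), Igkv (-0.72), kappa J (-1.18), lambda (-0.71) and constant genes (-0.74) were lower, with adjusted p between 9.87e-13 and 0.00115. With an estimated correlation the lowest adjusted p of these 7 was 0.0845. Without small pre-B KO replicate 1 the distal (-0.45), lambda (-0.30) and constant (-0.44) lists lost their calls. Values that moved while called were, without WT replicate 1, proximal (-1.82) and other Ighv (-0.75), without WT replicate 2, distal Ighv (-0.09), Igkv (-0.44) and lambda (-0.42), and without KO replicate 2, distal Ighv (-0.45) and Igkv (-1.18). Among constant genes Ighd had -1.46 (SE 0.21) and Ighm -0.88 (SE 0.21), neither called. The heavy chain D and J list did not pass (-0.11, adjusted p = 0.475).

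Further lists that passed in small pre-B KO were interferon-stimulated genes (median 0.30, adjusted p = 4.13e-05, 0.522 with an estimated correlation), mitochondrially encoded mRNAs (-0.47, adjusted p = 7.61e-05, 0.574 with an estimated correlation) and replication-dependent histones (-0.28, adjusted p = 0.00184, 0.635 with an estimated correlation). V(D)J recombination and end joining (-0.28, adjusted p = 0.0461, 0.612 with an estimated correlation) and p53 target genes (-0.17, adjusted p = 0.0294, 0.266 with an estimated correlation) passed as well. Only the interferon list kept its call without any single library, with 0.17 without small pre-B WT replicate 2. Mitochondrial mRNAs lost theirs without KO replicate 1 (-0.23) and were at -0.74 without KO replicate 2. Histones lost theirs without KO replicate 2, where the median turned to 0.08, and were at -0.59 without KO replicate 1. The recombination list lost its call without any of small pre-B WT replicate 2 (0.00), KO replicate 1 (-0.21) and KO replicate 2 (-0.27), and also without either pre-pro-B WT library. The p53 list lost its call without small pre-B WT replicate 2 (-0.13), KO replicate 1 (-0.02) or KO replicate 2 (-0.20). The splicing lists did not pass, with a median of 0.08 for the U4/U6.U5 tri-snRNP (adjusted p = 0.328) and 0.01 for U1 and U2 snRNP and SR proteins (adjusted p = 0.875). Nor did S phase (0.11, adjusted p = 0.177), G2 and mitosis (0.07, adjusted p = 0.343), MYC and ribosome biogenesis (-0.03, adjusted p = 0.343), multipotent progenitor genes (0.14, adjusted p = 0.254), chromatin loop factors (-0.05, adjusted p = 0.131), the BCL2 family (-0.08, adjusted p = 0.943) and the stress response list (0.08, adjusted p = 0.943). With an estimated correlation no list passed at this stage, and fry called only the proximal Ighv list (adjusted p = 0.0352).

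**Figure D3:**
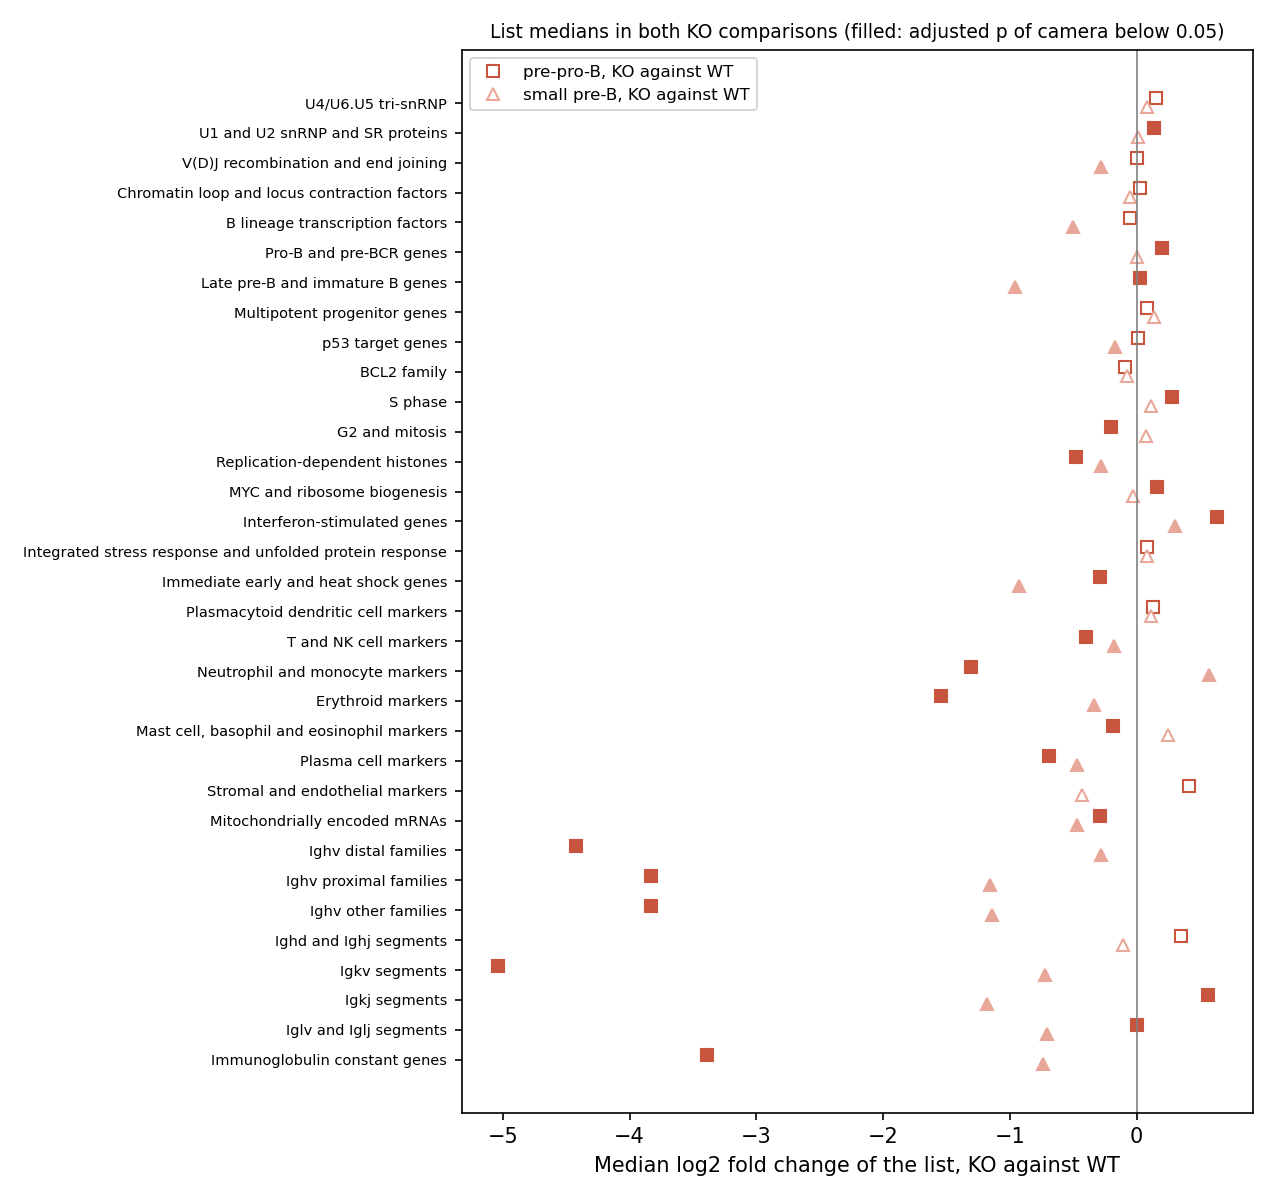
Median log2 fold change of KO against WT for the 33 gene lists tested, at the pre-pro-B stage (squares) and the small pre-B stage (triangles), with genes at 0 counts set to their bound. Filled symbols passed camera with a preset correlation. The Ighv and Igkv lists lie between -3.83 and -5.04 at the pre-pro-B stage, and neutrophil and monocyte markers lie at -1.31 at the pre-pro-B and at 0.57 at the small pre-B stage.

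Whether the KO effect differed between the stages was tested as an interaction. In it, stage, Cre line and any difference in processing between the stages cannot be separated. It called 21 genes, 20 with a higher value at the small pre-B stage, and 14 of them were immunoglobulin genes. Jchain (difference 5.61 on the log2 scale, SE 0.57, adjusted p = 0.0133), Rhou (2.56, adjusted p = 0.0388), St3gal5 (2.23, adjusted p = 0.0476) and Trp53inp2 (1.77, adjusted p = 0.0396) were those named by the rule. Over 15 alternative settings Jchain was called in 12 and each of the other 3 genes in 7. The lone gene with a lower value was Rpl36a-ps3 (-3.59), named after its value was seen. The sum of the other Ighv families differed by 5.24 (SE 0.53, adjusted p = 0.016), and that of the proximal families passed as well (adjusted p = 0.00244). Limma-voom ended both calls (5.11 with adjusted p = 0.128, and adjusted p = 0.0948 for the proximal families), and the call of the other Ighv families also ended without small pre-B WT replicate 1 (5.08), WT replicate 2 (5.43) or KO replicate 2 (5.13). The distal families (5.02, adjusted p = 0.052) and the Igkv segments (4.46, adjusted p = 0.0543) lay just above the threshold. Of the sums not called in the main fit, 3 passed by DESeq2 and 3 with no filter. The count was 405 by DESeq2, 4 by limma-voom and 11 with the stricter filter, and 0 with immunoglobulin genes left out. Without a single library it was 3 (small pre-B WT replicate 2), 4 (small pre-B WT replicate 1), 12 (small pre-B KO replicate 2), 52 (pre-pro-B KO replicate 2), 81 (pre-pro-B WT replicate 1) and 679 (pre-pro-B KO replicate 1).

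No gene was called in the same direction in both KO comparisons in the 8-library fit, which called none at the small pre-B stage. Of the 55 genes called in pre-pro-B KO, 38 had the same sign in small pre-B KO, 25 of the 29 immunoglobulin genes and 13 of the 26 others. In the fits of each stage alone, 6 genes were called lower in both against 0.293 expected (Fisher's exact test, p = 4.01e-07): Ighv1-80, Ighv3-6, Ighv8-8, Igkv1-110, Igkv17-127 and Reln. Genes are not independent, least of all segments of a locus, so this p is a description.

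Between the WT stages 8682 genes differed, 4349 higher and 4333 lower in the small pre-B libraries. The libraries of both stages held markers of other marrow cells, so these differences cannot be credited to B lineage precursors alone. Higher were Ms4a1, the B cell antigen CD20 (log2 fold change 6.61, SE 0.46), Cd19 (4.17, SE 0.90), Cd79a (3.52, SE 0.33), the recombinase gene Rag1 (2.86, SE 0.39) and Pax5 (3.58, SE 0.60). The collagens Col1a1 (7.26, SE 0.63) and Col1a2 (7.13, SE 0.76), Cacna1i (6.21) and Bglap (6.16) were higher as well. Lower were Myh13 (-7.25, SE 0.53), Il17d (-7.23, SE 0.40), Fyb2 (-6.57, SE 0.19), Sntg2 (-6.00) and C8a (-5.82), as well as Irf8 (-3.78, SE 0.20), Tcf4 (-3.57, SE 0.17), the latter a regulator of plasmacytoid dendritic cells, and Dntt (-2.27, SE 0.19). All 26 G2 and mitosis genes were called higher in the small pre-B libraries (median 2.01), as were 26 of 28 S phase genes (1.26) and all 24 neutrophil and monocyte markers (2.73). Plasmacytoid dendritic cell markers were called lower in 16 of 18 members (median -4.35) and T and NK cell markers in 24 of 28 (-2.01). Camera called 17 of 33 lists, and none with an estimated correlation, where the lowest adjusted p was that of plasmacytoid dendritic cell markers (0.119). Besides, 86 genes on unplaced scaffolds held 15030 to 16570 counts in each pre-pro-B library and 0 in each small pre-B library. This argues against equal handling of reads on these scaffolds at both stages, which the labels do not describe. Differences in processing are therefore confounded with stage.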

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

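All tests of explanations in this part were chosen after the results had been seen. The values below differ between the stages by the test of the difference itself, small pre-B KO effect minus pre-pro-B KO effect on the log2 scale. The test called 21 genes, among them Jchain (5.61), Rhou (2.56), St3gal5 (2.23) and Trp53inp2 (1.77). The family sums of the proximal Ighv segments (8.01) and of the other Ighv segments (5.24) differed too. Among lists, the medians were 4.52 for distal Ighv, 5.50 for proximal Ighv and 4.82 for Igkv segments, and these 3 also passed with an estimated correlation (adjusted p = 0.0135, 0.0435 and 0.014). Without pre-pro-B WT replicate 2 the distal median was 2.74 and the Igkv median 2.78, and without WT replicate 1 the proximal one was 3.14, all still called. Fitted values of segments at 0 counts in pre-pro-B KO enter these figures, so none of them is a bound, and the proximal sum rests on 3 KO counts.

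The other lists passed with the preset correlation only. Their medians were 3.53 for other Ighv segments, 2.66 for constant genes and -1.74 for kappa J segments (adjusted p = 0.138, 0.125 and 0.125 with an estimated correlation). Neutrophil and monocyte markers were at 1.71 (0.282 with an estimated correlation) and p53 target genes at -0.18 (0.282). Late pre-B and immature B genes were at -0.67 (0.602) and G2 and mitosis genes at 0.27 (0.7). The rest all had an adjusted p of 0.667 with an estimated correlation: erythroid markers at 1.20, mast cell, basophil and eosinophil markers at 0.22, stromal and endothelial markers at -0.41, Pro-B and pre-BCR genes at -0.55, B lineage transcription factors at -0.28, interferon-stimulated genes at -0.23, MYC and ribosome biogenesis genes at -0.16, and U1 and U2 snRNP and SR proteins at -0.09. These 8 lists, the p53 and the G2 and mitosis list each lost the call without some single library. The median turned to -0.05 for G2 and mitosis genes without pre-pro-B WT replicate 1, and to 0.21 for Pro-B and -0.63 for mast cell genes without pre-pro-B KO replicate 2. Among the lists of this paragraph that kept their calls throughout, 3 medians moved by more than 1.5 times. They were 1.96 for other Ighv segments without pre-pro-B WT replicate 2, 2.73 for neutrophil and monocyte markers without pre-pro-B KO replicate 1 and -0.43 for late genes without small pre-B KO replicate 1. Lists that lost the call elsewhere moved as well, such as erythroid (2.01) and mast cell markers (2.83) without pre-pro-B KO replicate 1.

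The first pattern is the lower level of transcripts of immunoglobulin variable segments and class-switched constant genes in the pre-pro-B libraries labelled KO. A lower carry-over of all other marrow cells is argued against as the whole cause, since the neutrophil median lay 3.74 above the Igkv median (bootstrap interval 2.60 to 4.56). The interval covers list members and not the spread between libraries. By library, neutrophil and monocyte markers made up 0.764 and 0.886% of counts in WT and 0.426 and 0.149% in KO. Igkv segments had 441 and 827.7 CPM in WT and 24.7 and 9.5 CPM in KO. RNA of antibody-secreting cells in the WT libraries is a possible source that the test cannot settle. The 8 plasma cell markers other than Jchain and the dendritic cell gene Mzb1 had a median log2 fold change of -0.69 (interval -1.18 to -0.32). Jchain and Igkc stood at 266.4 and 904 CPM in WT, and class-switched Ighg1 and Ighg2c fell with them. The plasma cell median fell less than those of neutrophil (-1.31) and erythroid (-1.54) markers. It fell far less than that of Igkv segments (-5.04 with genes at 0 counts at their bound). Jchain, left out of this median, was the 1 plasma cell marker called over all genes, with a log2 fold change of -5.98. The median of the other 8 therefore does not measure how strong such a source was. A lower carry-over of marrow cells would lower plasma cell markers as well. Cd28 and Irf4 of these 8 are also on other lists, and the labels give no gate that would show if antibody-secreting cells were removed. Fewer precursors with a rearranged locus, the biological explanation the design names, would not by themselves lower class-switched constant genes. The 5 tested, 3 of them called, had a median log2 fold change of -6.62 (bootstrap interval -9.77 to -2.94). The test was chosen after this fall had been seen, so it restates the fall. Its interval covers the 5 genes and not the spread between libraries. For the V segments, the D and J sum cannot tell fewer such precursors from RNA of antibody-secreting cells. The D and J sum at 0.34 (interval -0.28 to 0.96) did not fall by the 4 that would exclude fewer such precursors. Fewer precursors do not predict the lower plasma cell markers. Precursors as the source of the V transcripts do not by themselves predict the WT levels either. Igkv segments had 634.4 ± 273.4 CPM in pre-pro-B WT, near the 683.8 ± 58.2 CPM in small pre-B WT. Cd79a in pre-pro-B WT was at 8.7% of its small pre-B WT level. A loss of antibody-secreting cells might itself follow from the deletion or from Cre.

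The next pattern is the fall of late B lineage genes beside the rise of neutrophil genes in the small pre-B libraries labelled KO. A lower share of all B lineage cells would not by itself predict that the Pro-B and pre-BCR median lay 0.96 above the late median (bootstrap interval 0.53 to 1.43). Erythroid and neutrophil markers also moved in opposite directions. The test cannot exclude a lower share as part of the cause, because the Pro-B and pre-BCR list was split, with 11 members higher and 10 lower. Cd79b (-0.76) and Blnk (-0.45) were among the lower ones, and B lineage transcription factors had a median of -0.50. Fewer immature and mature B cells in the sort may account for it. The mean log2 fold change of Vpreb1 and Igll1 was 0.65, and neither gene was called. Because the 8-library fit called 0 genes at this stage, this test cannot decide. A change within cells that lack Usp39 stays open, because Usp39 itself (adjusted p = 1) gives no sign of which cells had deleted it. These explanations cannot be told apart here, and an effect of cd19-cre without deletion was not tested.

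The last pattern is that Usp39 counts were not lower in the libraries labelled KO. At the pre-pro-B stage most RNA may come from cells that do not express the mb1-cre host gene, but this was not settled. Cd79a in WT was 8.70% of its level in small pre-B WT, and Siglech stood at 2547 CPM or more in every pre-pro-B library. A ratio between stages cannot tell fewer expressing cells from a lower level per cell. At the small pre-B stage neutrophil and monocyte markers made up 8.61% of counts in KO on average, and S100a9 had the most counts of any gene in every library. The share of these 24 genes sets no upper limit on the RNA of other cells, so the test cannot tell how much there was. A deletion that leaves most of the 13 exon blocks in the transcript cannot be told apart from no deletion, since the files hold a single count per gene. A wrong label was not tested.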

How the results depend on the processing

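Called results kept their direction nearly throughout but often lost the call, and counts of called genes moved widely. The cause was not tested. Of results called in the main fit, 3 of 24 named genes, 3 of 4 family sums and 5 of 22 lists kept the call in every setting for pre-pro-B KO, 0 of 19 lists for small pre-B KO, and 2 of 17, 0 of 2 and 3 of 18 for the difference between stages. For the WT stages 126 of 134 named genes, 3 of 4 sums and 0 of 17 lists did. Jchain held in 16 of 16 settings for pre-pro-B KO, and Iigp1, Thbs1 and Slco4c1 in 6 and Lrrk2 in 5. With 2 libraries per group, 1 library can set the spread of a gene. The 55 genes of pre-pro-B KO became 695 with no filter, 338 by DESeq2, 12 by limma-voom and 9 with immunoglobulin genes left out, and 40 to 557 without single libraries. The 0 genes of small pre-B KO became 626, 160, 0 and 0 in that order, 239 in the fit of the stage alone, and 0 to 15 without single libraries. The 21 genes that differ between stages became 872, 405, 4 and 0, and 11 with the stricter filter, and 3 to 679 without single libraries. Genes called in both KO comparisons went from 0 to 86 with no filter, 23 by DESeq2 and 6 in the fits of each stage, and 0 to 3 without single libraries. With the replicate number as a block the counts were 110, 3 and 65. DESeq2 size factors (57, 0 and 23) and, for pre-pro-B KO, the stricter filter (50) and the fold threshold (54) left them within 1.5 times, and the 8682 genes of the WT stages stayed within that bound in all settings. In the 4-library fits, DESeq2 called 143 and 1158 in place of 37 and 239, and leaving out libraries gave 76 to 503 and 5 to 1569, both added after the data were seen.

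Usp39 in pre-pro-B KO ranged from -0.34 to 0.02 without single libraries. The family sums kept their direction except, without single libraries, for D and J segments in pre-pro-B (-0.33 to 0.79), lambda segments in small pre-B (-0.95 to 0.20) and in the difference between stages (-0.21 to 0.93), and distal Ighv (-0.03 to 1.01) and Igkv (-0.29 to 0.63) in the WT stages, none called. The other Ighv sum in pre-pro-B KO lost its call by limma-voom (-5.74), as did the other Ighv (5.11) and proximal (8.31) sums for the difference between stages. With no filter, lambda segments in pre-pro-B (-0.73) and, in small pre-B, proximal Ighv (-1.16), other Ighv (-0.64), Igkv (-0.75) and kappa J (-1.25) sums passed. DESeq2 called proximal Ighv (-1.15) and kappa J (-1.25), and the fit of the stage called these (-1.21 and -1.30) and Igkv (-0.80). Without single libraries proximal Ighv ranged from -1.43 to -0.92 and kappa J from -1.44 to -1.05. Called lists whose median or test turned without a library were, in pre-pro-B, G2 and mitosis (-0.45 to 0.05), mitochondrial mRNAs (-0.82 to 0.11, and 0.10), Pro-B and pre-BCR (-0.19 to 0.52), late pre-B (-0.14 to 0.11) and lambda (0.00, and 0.15 and 0.02 without WT replicate 2 and KO replicate 1), both tested as lower throughout, and mast cell markers (-2.92 to 0.70). In small pre-B they were histones (-0.59 to 0.08) and T and NK cells (-0.31 to -0.01 by median, the mean having turned). For the difference between stages they were mast cell markers (-0.63 to 2.83), G2 and mitosis (-0.05 to 0.50) and Pro-B genes (-0.71 to 0.21). Depth limits single segments, of which 13 called ones had 0 KO counts.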

Other observations

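A few V segments held much of the counts in the pre-pro-B WT libraries, though counts per segment do not count rearrangements. In WT, Igkv1-110 alone held 40.8 and 52.4% of the Igkv counts and Ighv1-81 held 18.1 and 33% of the Ighv counts, and the effective number of Ighv segments was 15.7 and 7.8. In the small pre-B libraries that number was 36.9 and 43.5 in WT and 41.5 and 29.3 in KO, with no segment above 9.7% of the Ighv counts. The pre-pro-B KO libraries held 305 and 107 Ighv counts in all, of which Ighv1-81 took 63.3% in replicate 1 and Ighv1-23 took 13.1% in replicate 2. Distal families made up 82.3 and 91.3% of distal plus proximal counts in pre-pro-B WT and 83.8 and 83.4% in small pre-B WT, against 87.1 and 93.1% in small pre-B KO. In pre-pro-B KO they made up 100 and 96.6%, of only 283 and 89 counts.

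Mid1 stood at 66.5 and 99.9 CPM in pre-pro-B WT and 116.1 and 124.1 CPM in pre-pro-B KO, and at 17.1 and 19.8 CPM in small pre-B WT against 145.5 and 78.6 CPM in small pre-B KO. The pseudogene Gm8225 had 6 counts over both pre-pro-B WT libraries and 565 over both KO libraries, and Rpl10-ps1 had 235.1 and 196.6 CPM in WT and 69.0 and 79.1 CPM in KO. Pre-pro-B KO replicate 2 lay apart from the other pre-pro-B libraries on the principal component that carried 6.1% of the variance, at -60.8 against 0.6 to 40. It had the lowest share of neutrophil and monocyte markers, 0.149%, and among the pre-pro-B libraries the highest Vpreb1 (38.5 CPM) and Igll1 (70.2 CPM).

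Loss of a spliceosome component might lower the counts of genes with many exons more than those of genes with few. This test was planned before its result was seen, and a Spearman's rho below -0.1 at both stages was asked for. Across 17580 genes, which are not independent replicates, rho between log2 fold change and exon number was -0.041 in pre-pro-B KO (bootstrap interval -0.057 to -0.025) and 0.019 in small pre-B KO (0.004 to 0.034). Both lie above the bound, so no effect of that size showed in the gene counts of these libraries. Usp39 counts were not lower in the libraries labelled KO, so the share of cells that had lost Usp39 is unknown. The test therefore cannot exclude such an effect in cells without Usp39. The median log2 fold change of genes with over 20 exon blocks was -0.053 and 0.011, and that of genes with 1 exon block -0.031 and 0.003. Retained introns and exon skipping need not change gene counts and were not tested.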
